A study of Mus musculus with 21 samples.

How the data were processed

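RNA-seq read counts of whole mouse liver were analysed for 21 libraries in 4 groups. The groups combine the genotype (wild type, WT, or Mboat7 deleted in hepatocytes, KO) with the diet (chow, or a high-fat diet low in methionine and deficient in choline, HFMCD). There were 6 WT and 7 KO libraries on chow and 4 WT and 4 KO libraries on HFMCD. Per the labels' protocols, livers were perfused with PBS and kept in RNAlater, total RNA was taken with an RNeasy kit, and libraries followed standard Illumina protocols. HFMCD was given for 6 weeks to mice that were 6 to 8 weeks old at the start, and chow mice were 10 weeks old. Diet therefore went together with age and with the number ranges of the animals (102 to 110 for HFMCD and 317 to 346 for chow), so that a batch of either kind cannot be told apart from diet.

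The authors deposited 1 file per library with raw read counts per gene symbol, and no normalization was recorded for them. CASAVA 2.17, STAR 2.6.1d, featureCounts 1.6.1 and the build GRCm38 were named, per the submitters' processing notes, without a role for each. The annotation release, the strand setting of the counting and any read filter were not stated. All 55418 symbols of the files were found in GENCODE release M21 on GRCm38, from which the positions printed were taken. Exons of 73 of the 253 named genes lie over a gene on the other strand, and without a stated strand setting reads of such pairs cannot be told apart. Genes with near-identical copies (members of the Cyp2c, Cyp3a, Cyp4a, Sult2a, Sult3a, Mup, Saa, Gsta, Acot and haemoglobin families) are uncertain, since the counting could split their reads.

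Totals ran from 17502231 to 25822972 counts per library, and 19919 to 22261 genes had a read. A pairwise check of libraries within each group found 0 identical pairs. Reads were not reduced to molecules by identifiers, so bounds from a count of 0 and exact (Clopper-Pearson) 95% intervals of ratios cover counting error only.

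Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes with too few reads were removed by filterByExpr with the 4 groups, which left 15677 genes. Libraries were scaled by TMM. One quasi-likelihood model with 4 group means and robust dispersions was fitted to all 21 libraries, with no covariate, and 5 contrasts were tested by two-sided F tests: KO against WT on each diet, HFMCD against chow in each genotype, and the difference of the KO effect between the diets. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a contrast. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of F. CPM, the usual unit of counts relative to the library total, used the TMM-scaled total of the tested genes, and log2 CPM used a prior count of 2. Group values are means with the standard deviation (SD). The calls of both KO contrasts were compared by Fisher's exact test, one-sided, over the genes tested in both, without Mboat7; these contrasts share no library.

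Lists of genes (33) for pathways, liver cell types and tissues that a dissected liver could carry were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast. Camera with the correlation estimated per list, and fry, which asks whether a list's genes move on balance in 1 direction, were run beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone. The score of a list is the mean log2 CPM of its tested members, and scores were compared by exact permutation tests, two-sided.

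The groups, the models, the 33 lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took, for each contrast, Mboat7; the called genes with a mean of at least 2 CPM in the higher group and no overlap of the libraries of both groups, of which the 8 largest and the 8 smallest log2 fold changes were named (5 and 5 for HFMCD against chow in KO and, with no overlap asked, for the difference of the KO effect), leaving out clone and model names; up to 4 called members with the smallest p of each list described; and, where fewer than 5 genes were called, the 5 with the smallest p as values. Some genes that the rule names are not reported here. Other genes named (Dmbt1, Muc6, Ttn, Myh11, Col1a1, Malat1, Neat1 and further list members given as values) were chosen after their values were seen. So were 6 marker lists: gallbladder and gland mucosa, smooth muscle, mesothelium, skeletal muscle, fasting-induced genes and nuclear long RNAs.

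The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in at least 4 libraries, an added threshold of 1 on the absolute log2 fold change, a fit to the compared groups only, and leaving out each library in turn. Fits without KO chow replicates 1 and 7, fits without all 4 chow libraries rich in Dmbt1, and limma-voom with a variance per group were added after the data had been seen. No library was left out of the results reported first.

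The steps were tested on simulated counts for 15677 genes with 200 changed genes. For KO against WT on chow, edgeR recovered 50.7% of genes changed by 0.5 on the log2 scale, 79.1% of those changed by 1 and 89.4% of those changed by 2, and 3 of its 149 calls were unchanged genes. For KO against WT on HFMCD the shares were 17.9%, 53.7% and 86.4%, with 10 unchanged genes among 115 calls. For HFMCD against chow in WT they were 40.3%, 70.1% and 84.8%, with 4 among 134. For HFMCD against chow in KO they were 29.9%, 70.1% and 83.3%, with 8 among 130. For the difference of the KO effect they were 13.4%, 53.7% and 69.7%, with 5 among 96. With DESeq2, unchanged genes were 10 of 159 calls for KO against WT on chow, 25 of 138 on HFMCD and 18 of 121 for the difference. With limma-voom they were 3 of 143, 19 of 126 and 4 of 92. In a simulated rise of the cholangiocyte list in KO against WT on HFMCD, camera called that list and 0 others. Simulated genes were drawn independently of each other, with the same dispersion in both diets and no library that carried other tissue. The simulations therefore cannot show false calls that come from correlated genes, from unequal spread or from such libraries. Figures were drawn with Python 3.11.15.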

Results

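Transcript levels were measured by RNA-seq in whole livers of mice with Mboat7 deleted in hepatocytes (KO) and of wild-type mice (WT), at steady state on chow and on a high-fat diet low in methionine and deficient in choline (HFMCD). Mboat7 encodes an acyltransferase that attaches arachidonic acid to lysophosphatidylinositol. The 6 WT and 7 KO libraries on chow held 17502231 to 23058789 counts, and the 4 WT and 4 KO libraries on HFMCD held 22617598 to 25822972. Albumin was the most abundant transcript, with 5.39% to 8.96% of the counts of a library. The series title names fibrosis after loss of hepatic Mboat7, so genes of matrix, stellate cells and other liver cell types were followed together with those of lipid metabolism.

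Mboat7 (chromosome 7, 3677789 to 3693523, minus strand, GRCm38) was lower in every KO library than in every WT library of the same diet. On chow it averaged 36.2 CPM ± 2.72 (SD, n = 6) in WT and 21.3 CPM ± 1.77 (SD, n = 7) in KO, a log2 fold change of -0.76 (SE 0.07, edgeR adjusted p = 3.9e-06). On HFMCD it averaged 36.3 CPM ± 1.47 (SD, n = 4) in WT and 18.9 CPM ± 2.24 (SD, n = 4) in KO, a log2 fold change of -0.94 (SE 0.09, edgeR adjusted p = 7.5e-06). The difference between those effects was -0.18 (SE 0.12, edgeR adjusted p = 0.66). HFMCD against chow gave a log2 fold change of 0.00 in WT (edgeR adjusted p = 0.98) and -0.17 in KO (edgeR adjusted p = 0.068). Exons of Mboat7 overlap those of Tsen34 on the other strand over 277 bases, and the labels do not name the exons removed, so the remaining counts were not divided further.

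**Figure D1:**
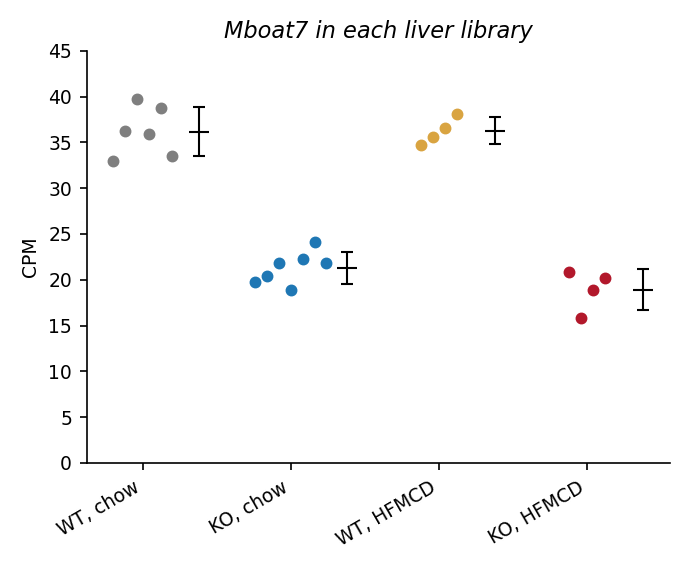
Mboat7 in CPM (y axis) in each liver library, by genotype and diet (x axis). Points are libraries, and the horizontal marks with bars are group means ± SD (n = 6, 7, 4 and 4); KO libraries sit between 15.8 and 24.1 CPM and WT libraries between 33.0 and 39.7 CPM.

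The first principal component of log2 CPM held 69.6% of the variance and separated HFMCD from chow livers in both genotypes. The second held 4.4% and set KO chow replicates 1 and 7 apart from the other livers, at -39.5 and -48.4.

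**Figure D2:**
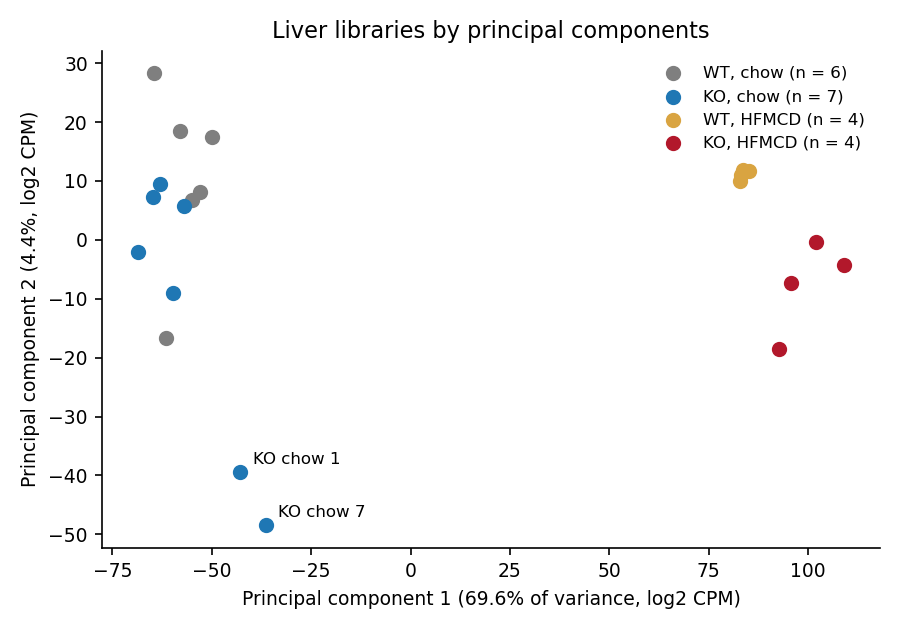
First and second principal components of log2 CPM (axes in component units, with the percentage of variance) for 21 libraries. Each point is a library coloured by group; the diets lie apart along the first component, and KO chow replicates 1 and 7 lie lowest along the second.

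The comparison of KO with WT on chow asked which transcripts change with loss of hepatocyte Mboat7 at steady state. In KO livers Cyp2c70, which makes muricholic acids in the mouse (chromosome 19, 40153353 to 40187333), rose from 157 CPM ± 30.6 (SD, n = 6) to 319.3 CPM ± 107.1 (SD, n = 7), by 1.02 on the log2 scale (SE 0.16, edgeR adjusted p = 0.0049). Cpt1a, the carnitine palmitoyltransferase of the outer mitochondrial membrane, fell from 682 CPM ± 143 (SD, n = 6) to 457 CPM ± 70.6 (SD, n = 7). The lipid droplet protein gene Cidec fell by 2.30 on the log2 scale (SE 0.53, edgeR adjusted p = 0.035), and Apoa4, which encodes a lipoprotein component, fell by 2.12 (SE 0.38, edgeR adjusted p = 0.014).

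In all, 88 genes were called higher and 252 lower in KO on chow of 15677 tested. The other rises named by the fixed rule were Hells (log2 fold change 1.06), which remodels chromatin, Lrrc14b (0.88), the endosomal gene Wdr91 (0.81), Coprs (0.79), which recruits the arginine methyltransferase PRMT5 to histones, the histone H4 methyltransferase gene Kmt5a (0.62) and the magnesium transporter gene Cnnm4 (0.58). The other falls were Cgref1 (-2.07), Slc6a16 (-0.91), the cyclin D1 gene Ccnd1 (-0.80), the ephrin gene Efna5 (-0.66), Xrcc4 (-0.55), which acts in the joining of DNA ends, and Hykk (-0.53), a kinase of hydroxylysine breakdown. Their edgeR adjusted p-values lay between 0.0034 for Kmt5a and 0.047 for Ccnd1. Exons of Lrrc14b, Ccnd1, Xrcc4, Apoa4, Cideb, Shmt2, Jun and Elovl3 lie over a gene on the other strand.

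Of 22 tested genes of fatty acid oxidation 0 had a positive log2 fold change on chow, and the median was -0.31 (camera adjusted p = 4.5e-10; adjusted p = 0.797 with an estimated correlation). Cpt1a (-0.58) and Acadl (-0.31) were among 3 called lower, and 17 were lower when adjusted over the list alone. The score of this list was 0.36 lower in KO, with an exact permutation p = 0.00583. Among 22 genes of lipid droplets and triglyceride handling, Cidec and Cideb (-0.26) were called lower, 6 were lower when adjusted over the list alone, and the median was -0.19 (camera adjusted p = 0.0497; adjusted p = 0.797 with an estimated correlation). The periportal list fell by a median of -0.17 over 14 genes, of which Apoa4 alone was called, also when adjusted over the list alone (camera adjusted p = 0.039; adjusted p = 0.797 with an estimated correlation). NRF2 targets, genes of the antioxidant response, rose by a median of 0.15 over 17 genes (camera adjusted p = 0.039; adjusted p = 0.797 with an estimated correlation); Ugdh (0.47) was called, and 4 were higher and 1 lower when adjusted over the list alone.

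Single called members of lists that camera did not call included Pnpla7 (-0.63), a lysophospholipase gene, and Lclat1 (-0.38), a lysophospholipid acyltransferase gene, among 25 genes of phospholipid remodelling, of which 5 were lower when adjusted over the list alone. That list had a median of -0.01, a mean of 0.02 and a downward test direction (camera adjusted p = 0.66). Mvk (-0.72) was the called gene of 22 in cholesterol synthesis, with 2 lower when adjusted over the list alone. Bhmt2 (-0.52) and Shmt2 (-0.32), enzymes of methionine and serine metabolism, were called among 22 genes of methionine and choline metabolism, with 4 lower when adjusted over the list alone, a median of 0.01, a mean of -0.10 and a downward test direction (camera adjusted p = 0.42). The glycogen synthase gene Gys2 (-0.50) was called lower among 15 glucose genes, as it was when adjusted over the list alone. Jun (0.94) and Atf3 (0.61), genes of acute stress, rose, and the elongase gene Elovl3 (-1.07) fell.

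Some lists of matrix, dividing cells and cells other than hepatocytes were higher in KO on chow, with 0 members called over all genes or adjusted over the list alone in any of them. Kupffer cell, recruited macrophage, lymphocyte, neutrophil and cholangiocyte lists were not called, with camera adjusted p-values from 0.34 to 0.98. The matrix list had a median log2 fold change of 0.33 with 30 of 35 genes positive (camera adjusted p = 0.039), stellate cells 0.23 with 17 of 18 (camera adjusted p = 0.025), endothelial cells 0.17 with 15 of 16 (camera adjusted p = 0.025), cell cycle 0.35 with 18 of 21 (camera adjusted p = 0.040) and erythroid transcripts 1.13 with 6 of 6 (camera adjusted p = 0.039). Each of these 5 lists had an adjusted p = 0.797 with an estimated correlation. KO chow replicates 1 and 7 held transcripts of other tissues. Dmbt1, made by mucosal epithelia, stood at 95.6 and 54.6 CPM there, 41.7 and 27.6 CPM in WT chow replicates 3 and 5, and at most 0.60 CPM in the other 9 chow libraries. Ttn, the titin gene of striated muscle, stood at 331 CPM in KO chow replicate 7 and at most 0.73 CPM in any other chow library. Col1a1 stood at 25.9 and 20.8 CPM in KO chow replicates 1 and 7 against 2.94 to 9.62 CPM in the other chow livers. Without these 2 libraries the matrix median was -0.07, the stellate median 0.08, the endothelial median 0.15 and the cell cycle median 0.20. Camera called none of these 4 there. The erythroid list, with a median of 1.44, and fatty acid oxidation, with -0.33, were both called. With all chow libraries, erythroid scores overlapped, at 0.20 to 3.04 in WT and 1.31 to 4.05 in KO (exact permutation p = 0.155). They were highest in KO chow replicates 4 and 5, at 4.05 and 3.93.

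The number of genes called on chow depended on the libraries and on the fit. Only 2 genes, 1 in each direction, were called when the 13 chow libraries were fitted alone, and of the genes named Mboat7 alone was kept. The median SD of log2 CPM within groups was 0.255 on chow and 0.206 on HFMCD, and 86.8% of the genes called on chow varied more on chow, against 66.6% of all genes. Without KO chow replicates 1 and 7 the count was 144, of which 120 were among the 340. Leaving out WT chow replicates 3, 4, 5 or 6 gave 611, 183, 49 or 50 genes, and leaving out KO chow replicates 1, 3, 4 or 6 gave 91, 197, 109 or 53. Mboat7, Cyp2c70, Wdr91, Kmt5a, Cnnm4, Cgref1, Xrcc4, Pnpla7, Apoa4 and Bhmt2 passed with any 1 library left out, and the other named genes did not.

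**Figure D3:**
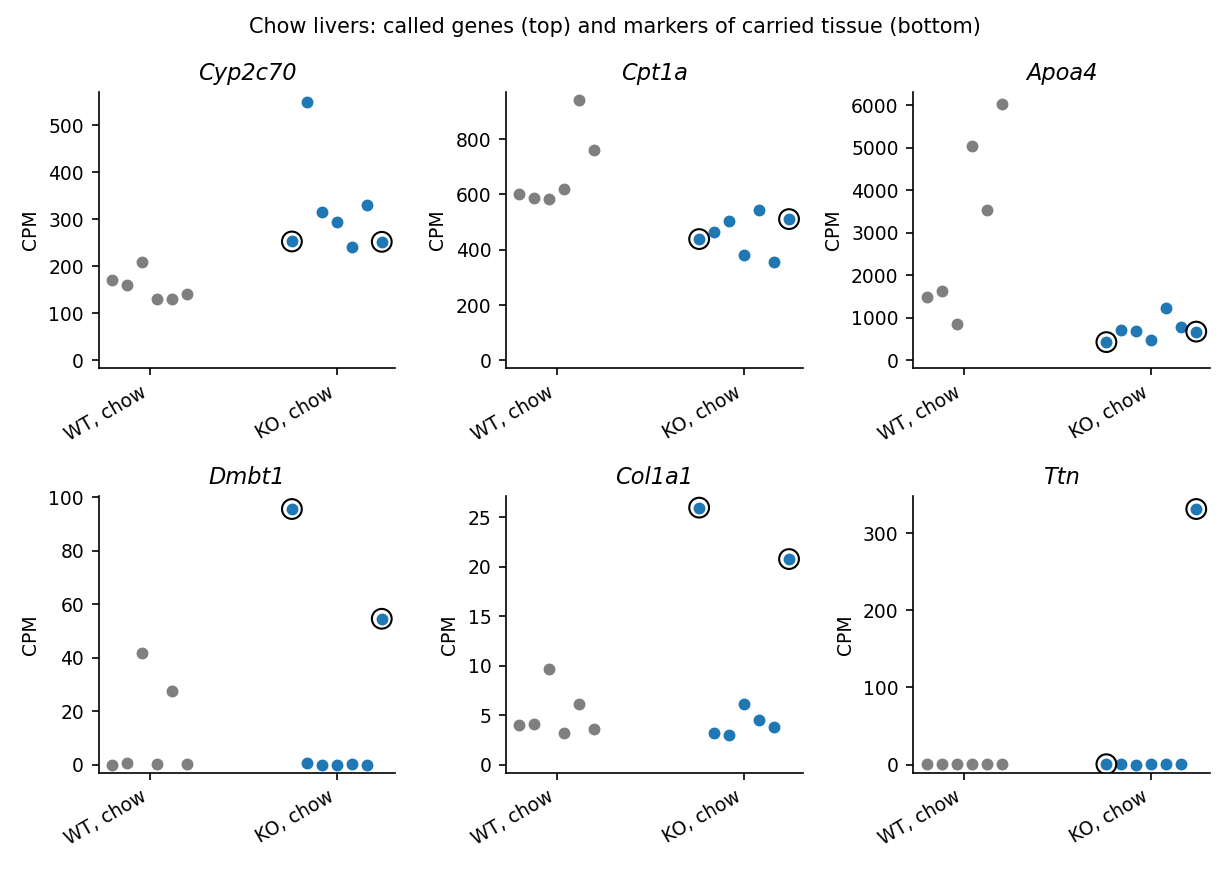
CPM (y axes) of Cyp2c70, Cpt1a and Apoa4 (top) and of Dmbt1, Col1a1 and Ttn (bottom) in each chow library by genotype. Points are libraries (6 WT, 7 KO) and rings mark KO chow replicates 1 and 7, which hold the highest Dmbt1 and Col1a1; Ttn reaches 331 CPM in replicate 7 only.

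The comparison of KO with WT on HFMCD asked the same of livers under a diet that injures them. KO livers held more transcripts of bile duct epithelium. Epcam, an epithelial adhesion gene (chromosome 17, 87635979 to 87651129), rose from 5.16 CPM ± 0.64 (SD, n = 4) to 18.0 CPM ± 4.67 (SD, n = 4), by 1.80 on the log2 scale (SE 0.37, edgeR adjusted p = 0.043). Spp1, which encodes osteopontin, rose from 186 CPM ± 16.7 (SD, n = 4) to 565 CPM ± 106.02 (SD, n = 4), by 1.5996 (SE 0.30, edgeR adjusted p = 0.035). Scd1, the stearoyl-CoA desaturase gene (chromosome 19, 44394455 to 44407879), stood at 159 CPM ± 33.4 (SD, n = 4) in WT and 1037 CPM ± 674 (SD, n = 4) in KO, a rise of 2.70 (SE 0.40, edgeR adjusted p = 0.010).

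Here 35 genes were called higher and 15 lower in KO. Further rises were the matrix metalloprotease gene Mmp7 (log2 fold change 2.79), the steroid dehydrogenase gene Akr1c18 (2.57), the collectin gene Sftpd (2.33), the cadherin gene Cdh6 (1.95), the chloride channel gene Cftr (1.90), the tight junction gene Cldn7 (1.81), the duct transcription factor gene Sox9 (0.94), Pkhd1 (0.82), which encodes a protein of primary cilia, and the replication gene Mcm6 (0.65). Falls were Elovl3 (-2.11), the sulfotransferase gene Sult2a8 (-1.40), the long noncoding RNA Ctcflos (-1.28), Angptl6 (-0.81), the collectin gene Colec10 (-0.78), Amigo2 (-0.61), the natriuretic peptide receptor gene Npr2 (-0.57) and Ecm1 (-0.53), a gene of stellate cells. Their edgeR adjusted p-values lay between 0.010 for Akr1c18 and 0.049 for Sftpd and Cftr. For each of these genes every KO library lay beyond every WT library on HFMCD, which the rule required of those named by the size of their change. Exons of Mmp7, Cftr, Pkhd1, Elovl3, Ctcflos, Angptl6, Amigo2 and Npr2 lie over a gene on the other strand.

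All 15 tested cholangiocyte genes had positive log2 fold changes on HFMCD, with a median of 1.49 (camera adjusted p = 3.0e-16; adjusted p = 0.0303 with an estimated correlation). Cftr, Cldn7, Epcam, Pkhd1 and Sox9 were called, and 11 were higher when adjusted over the list alone. Of 16 genes of pericentral hepatocytes, which surround the central vein, 0 were positive and the median was -0.35 (camera adjusted p = 2.9e-08; adjusted p = 0.0172 with an estimated correlation). None of these was called over all genes, and 8 were lower when adjusted over the list alone; Glul, the glutamine synthetase gene, was at -0.45 and Cyp27a1 at -0.43. In both lists the scores of the 4 KO livers lay apart from those of the 4 WT livers, by 1.22 for cholangiocytes and -0.34 for pericentral hepatocytes, each with an exact permutation p = 0.0286, the smallest that 4 against 4 can give. The scores of 10 of the 33 lists reached this p, where chance would give 0.943 if lists were independent; matrix (0.39), endothelial (-0.14), fatty acid synthesis (0.23), hepatocyte identity (-0.20), bile acid (-0.35), methionine and choline (-0.20), sex-biased (-0.43) and phospholipid remodelling scores (0.08) were the others.

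The other 14 lists called on HFMCD lost their call with an estimated correlation. Matrix genes had a median of 0.43 with 31 of 35 positive, 0 called and 3 higher when adjusted over the list alone (camera adjusted p = 5.1e-06; adjusted p = 0.387 with an estimated correlation). For Col1a1 the log2 fold change was 0.51 (SE 0.54) and for Col6a3 0.998 (SE 0.29), neither of them called. These SEs came from the fit to all 21 libraries, chow livers included. On HFMCD Col1a1 stood at 81.5 to 117.9 CPM in WT and 124.5 to 140.6 CPM in KO, without overlap. Recruited macrophages had a median of 0.34, with Spp1 called, a gene that duct cells express too, and 3 higher when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.368 with an estimated correlation). Cell cycle genes had a median of 0.38 with 21 of 21 positive, and Mcm6 was called, also when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.368 with an estimated correlation). Fatty acid synthesis had a median of 0.07, with Scd1 called and 3 higher when adjusted over the list alone (camera adjusted p = 0.025; adjusted p = 0.368 with an estimated correlation).

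Lists lower in KO on HFMCD included fatty acid oxidation, with a median of -0.37, 0 of 22 positive, 0 called and 10 lower when adjusted over the list alone (camera adjusted p = 1.8e-09; adjusted p = 0.229 with an estimated correlation). Its score was 0.38 lower in KO, with an exact permutation p = 0.114. Interferon-stimulated genes had a median of -0.39 with 2 of 20 positive and 0 lower when adjusted over the list alone (camera adjusted p = 9.2e-06, and adjusted p = 0.384 with an estimated correlation). The interferon score was lowest in KO HFMCD replicate 2, at 3.58, against 4.04 to 4.42 in the other KO livers and 4.30 to 4.59 in WT on HFMCD. Hepatocyte identity had a median of -0.22 with 1 of 19 positive and 0 lower when adjusted over the list alone (camera adjusted p = 1.4e-04; adjusted p = 0.098 with an estimated correlation). Bile acid synthesis and transport (-0.24, with 1 gene lower when adjusted over the list alone), methionine and choline metabolism (-0.21, with 1 higher and 1 lower), endothelial cells (-0.22, with 0), xenobiotic metabolism (-0.25, with Sult2a8 called and the 1 lower), cholesterol synthesis (-0.15, with 1 lower), sex-biased genes (-0.31, with Elovl3 called and the 1 lower) and lipid droplets (-0.15, with 0) were also lower. Camera adjusted p-values of these 7 lists ran from 1.7e-04 to 0.029, and the adjusted p ran from 0.098 to 0.594 with an estimated correlation.

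**Figure D4:**
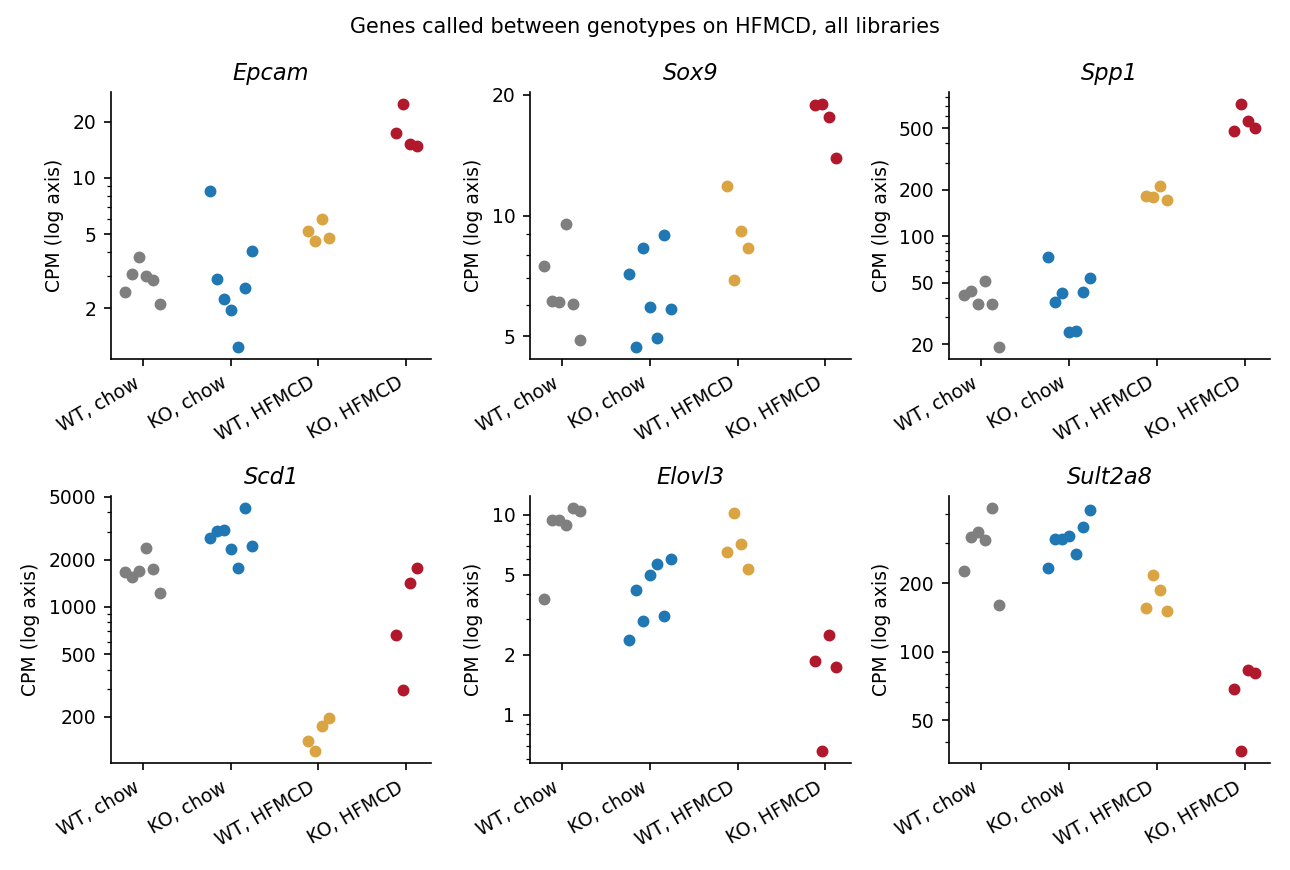
CPM (log y axes) of Epcam, Sox9, Spp1, Scd1, Elovl3 and Sult2a8 in each library by group. Points are libraries (n = 6, 7, 4 and 4); KO livers on HFMCD lie above WT livers on HFMCD for the top 3 genes and Scd1, and below them for Elovl3 and Sult2a8.

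The number of genes called fell with any 1 library of this comparison left out, which also leaves fewer libraries. Leaving out WT HFMCD replicates 1 to 4 gave 2, 1, 7 or 9 genes, and leaving out KO HFMCD replicates 1 to 4 gave 9, 3, 15 or 16; Mboat7 was the only one of 21 named genes called each time. The 8 HFMCD libraries fitted alone gave 296 genes, among which 18 of the 21 named genes remained and Scd1, Amigo2 and Mcm6 did not.

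Whether the effect of KO differed between diets was tested gene by gene and by list. With edgeR 0 genes were called, 1581 had an unadjusted p under 0.05, and the smallest adjusted p was 0.074. DESeq2 called 100 genes and limma-voom 10. In the simulation of this contrast, 18 of 121 DESeq2 calls, 4 of 92 limma-voom calls and 5 of 96 edgeR calls were unchanged genes. The 5 genes with the smallest p were Pkhd1 (difference of log2 fold changes 1.17, SE 0.20), Angptl6 (-1.13, SE 0.21), Lamc3 (1.501, SE 0.28), Ecm1 (-0.79, SE 0.15) and Amigo2 (-0.85, SE 0.17), with edgeR adjusted p = 0.074 for the first 4 and edgeR adjusted p = 0.078 for Amigo2. Pkhd1 stood at 5.97 CPM ± 1.02 (SD, n = 6) and 4.70 CPM ± 0.75 (SD, n = 7) in WT and KO on chow, and at 9.17 CPM ± 0.68 (SD, n = 4) and 16.3 CPM ± 2.46 (SD, n = 4) on HFMCD. Cholangiocyte genes had a more positive KO effect on HFMCD, with a median difference of 1.14 and 15 of 15 positive (camera adjusted p = 1.4e-10; adjusted p = 0.141 with an estimated correlation), and 6 passed when adjusted over the list alone. Pericentral genes had a more negative one, with a median of -0.31 and 3 of 16 positive (camera adjusted p = 4.1e-06; adjusted p = 0.0592 with an estimated correlation), and 3 passed when adjusted over the list alone. Endothelial, interferon-stimulated, xenobiotic and hepatocyte identity genes also had a more negative KO effect on HFMCD and recruited macrophage genes a more positive one, with camera adjusted p-values from 3.8e-05 to 0.0085 and an adjusted p from 0.333 to 0.645 with an estimated correlation. Without KO chow replicates 1 and 7, 84 genes were called, 65 with a more positive and 19 with a more negative KO effect on HFMCD.

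Few called genes were shared between the diets with edgeR, and DESeq2 shared 11. Of 88 and 35 higher genes 0 were shared, where 0.20 would be shared by independent lists, and of 252 and 15 lower genes 2 were shared, the deleted gene Mboat7 and Elovl3. Without Mboat7 1 was shared of 251 and 14, where 0.22 would be (Fisher's exact test, one-sided p = 0.202). Of the 340 genes called on chow, 241 (70.9%) had the same sign on HFMCD, of the 50 called on HFMCD 31 (62%) had the same sign on chow, and of all genes 56.6% did. Across all genes, which are not independent replicates, Pearson's r of both KO effects was 0.17.

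The comparison of HFMCD with chow asked what the diet does in each genotype. In WT livers 18 of 18 genes of recruited macrophages, 31 of 35 matrix genes and 18 of 21 cell cycle genes were called higher, and 18 of 22 genes of fatty acid oxidation and 11 of 19 of hepatocyte identity were called lower. None of these 5 lists kept its call with an estimated correlation, where the adjusted p ran from 0.143 to 0.350. Mmp12, the metalloelastase of macrophages, rose from 0.4 to 382 CPM (log2 fold change 9.92, SE 0.23, edgeR adjusted p = 2.8e-19), and Gpnmb, a glycoprotein gene of lipid-laden macrophages, from 0.5 to 459 CPM (9.74, SE 0.45, edgeR adjusted p = 2.8e-12). Scd1 fell by 3.42 on the log2 scale (SE 0.40, edgeR adjusted p = 7.0e-07). In WT 4541 genes were called higher and 5262 lower, and in KO 5284 and 5636. Of those called in both genotypes 8869 moved in the same direction and 8 in opposite directions, and Pearson's r across genes was 0.93 between these contrasts, which share no library.

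Ubd, an inflammation-induced ubiquitin-like gene, rose by 7.63 in WT and 9.38 in KO. In WT, Sprr1a had 0 counts on chow and was at least 223-fold higher on HFMCD, with 3 counts over the group as the floor. Genes with 1 to 3 counts over the chow group are given as ratios of summed counts with exact 95% intervals. In WT these were 570 (101.8 to 22558) for Gdf3, 430 (119 to 3561) for Gsta1, which encodes a glutathione transferase, 460 (82.1 to 18225) for Vsig8 and 414 (73.8 to 16388) for Slc7a11, which encodes the cystine transporter. In KO they were 252 (85.9 to 1226) for Sprr1a and 255 (70.1 to 2112) for Slc7a11, and Mmp12 (10.07) and Gpnmb (9.45) rose by about as much as in WT. The largest falls in WT were Serpina4-ps1 (at least 118-fold lower), AY036118 (-8.04), Cyp3a41a (-7.60), Sult3a1 (-7.46), Cyp2c69 (-7.40), Ccdc152 (-7.39), Cyp3a16 (-7.31) and Sult3a2 (-6.65). In KO they were Sult3a1 (-9.36), Cyp3a16 (-9.07), AY036118 (-8.95), Cyp2c69 (-7.71) and Sult3a2, with 2 counts over the HFMCD group and a ratio of chow to HFMCD of 495 (137 to 4089). Most of these falls are in families of cytochromes P450 and sulfotransferases, whose members can share reads.

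Recruited macrophage genes were called higher in 18 of 18 cases in both genotypes, among them Trem2 (6.12) and Lgals3 (4.65) in WT. Matrix genes were called higher in 31 and lower in 1 of 35 in WT, and higher in 32 and lower in 1 in KO; Mmp13 (6.46), Tgfbi (2.13) and Bgn (2.26) were examples in WT. Cell cycle genes were higher in 18 of 21 in WT and 20 in KO, with Cdk1 at 3.25 and 3.26. Cytokines and chemokines were higher in 18 of 20 in WT, with Ccl2 at 4.66, and higher in 17 and lower in 1 in KO. Neutrophil genes were higher in 10 of 10 in both genotypes, and stellate cell genes in 13 of 18 in WT, with Postn at 1.95, and in 12 with 2 lower in KO. Adjusted over the list alone, the counts were the same except for cell cycle genes in WT, where 19 were higher. Camera called these lists in both genotypes, with the largest adjusted p = 0.0044 for neutrophils in KO. With an estimated correlation they were not called, and for these 6 lists the adjusted p ran from 0.143 to 0.308 in WT and, with an estimated correlation as well, from 0.278 to 0.402 in KO.

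Metabolic lists moved too. Cholesterol synthesis was higher in 18 and lower in 1 of 22 genes in WT, with Idi1 at 3.10 and Mvk at 1.93 (camera adjusted p = 3.6e-05; adjusted p = 0.308 with an estimated correlation), and higher in 14 and lower in 1 in KO. Fatty acid oxidation was lower in 18 of 22 genes in WT, 19 when adjusted over the list alone, with Acadvl at -1.01 and Acot1 at -3.04 (camera adjusted p = 6.2e-05; adjusted p = 0.350 with an estimated correlation), and lower in 18 and higher in 1 in KO. Hepatocyte identity was lower in 11 of 19 genes in WT, with Hnf4a at -0.89 (camera adjusted p = 0.0079; adjusted p = 0.308 with an estimated correlation), and in 14 in KO. Cholangiocyte genes were higher in 6 of 15 in WT (5 when adjusted over the list alone; camera adjusted p = 0.073) and in 13 in KO, with Cftr at 3.63 and Sox9 at 1.40 (camera adjusted p = 4.3e-04; adjusted p = 0.398 with an estimated correlation).

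Signs of RNA make-up moved with diet. AY036118, a long noncoding RNA (chromosome 17, 39847113 to 39848035) that lies over Gm42418 on the other strand, stood at 34.7 to 106.6 CPM in chow livers and at most 0.33 CPM in HFMCD livers. Malat1 averaged 1486 CPM ± 159 (SD, n = 6) and 1386 CPM ± 214 (SD, n = 7) in WT and KO on chow, and 432 CPM ± 98.4 (SD, n = 4) and 362 CPM ± 72.1 (SD, n = 4) on HFMCD. Mitochondrial transcripts took 3.92% ± 0.25 (SD, n = 6) of counts in WT on chow and 5.54% ± 0.46 (SD, n = 4) in WT on HFMCD. In KO they took 4.16% ± 0.32 (SD, n = 7) on chow and 6.09% ± 0.62 (SD, n = 4) on HFMCD. Diet, age and any batch cannot be told apart in these groups.

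**Figure D5:**
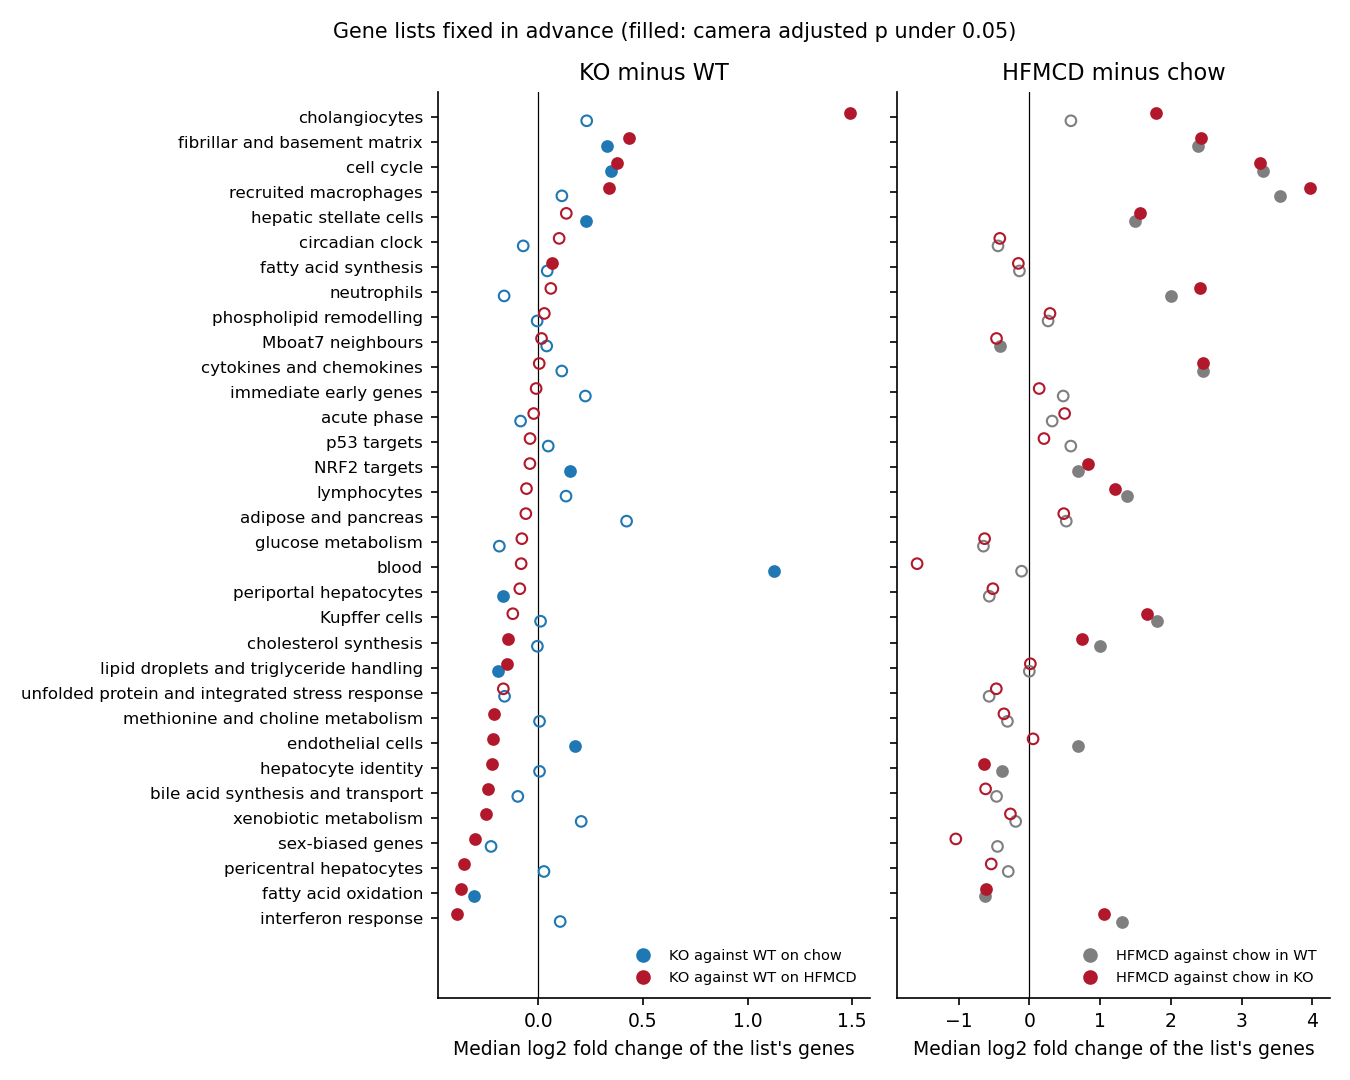
Median log2 fold change (x axes) of the genes of each list fixed in advance (y axis), for KO against WT (left) and HFMCD against chow (right). Filled points passed camera at an adjusted p under 0.05; cholangiocytes reach 1.49 in KO on HFMCD and recruited macrophages 3.54 and 3.97 in HFMCD livers.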

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

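For the count of genes changed in KO on chow, the splits were set in advance, and the variance per group, the feeding test and the reading of the fit of chow libraries alone were chosen only after the count was seen. Of 100 divisions of the chow libraries into groups of 6 and 7, only the real 1 gave as many genes (340, highest other 113). Whether the spread estimated jointly with HFMCD libraries raised the count stays open: 2 genes were called with the chow libraries alone, a fit that also has fewer libraries, but limma-voom with a variance per group called 170 against 113 with quality weights. A difference in feeding at collection stays open: fasting-induced genes that were not called were 0.31 lower in KO, with an exact permutation p = 0.127. Lower Cpt1a and Cidec could come from feeding as well as from loss of Mboat7, and collection times that were recorded would tell them apart.

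For the matrix list on chow, both tests were chosen only after the result was seen. The rise rested on KO chow replicates 1 and 7, since the median was -0.0653 without them and 0.0495 without all 4 chow libraries rich in Dmbt1. Both replicates had the highest matrix scores on chow, so leaving them out had to lower the median. That cannot tell carried tissue from a matrix rise in those livers. A smaller rise in KO livers in general stays open: of the 5 KO chow libraries with at most 0.60 CPM of Dmbt1, 1 had a matrix score above the highest of the 4 such WT libraries. The scores were 3.91 and 3.83 in KO chow replicates 1 and 7 and 2.48 to 2.92 in the other KO livers. In WT they were 2.61 to 2.85 in those 4 livers and 3.06 and 3.17 in replicates 3 and 5, which are rich in Dmbt1.

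For the cholangiocyte list on HFMCD, all 3 tests were chosen only after the result was seen. Gallbladder mucosa of the make-up seen on chow was argued against, since the highest Dmbt1 in a KO HFMCD library was 0 CPM, where 165 to 278 CPM would go with the Epcam there, although 2 other mucosal genes were higher in KO than in WT on HFMCD (Gabrp 0.29 to 1.47 CPM against at most 0.121, Aqp5 0.109 to 0.404 CPM against at most 0.082). A lower share of hepatocytes stays open: their identity score was 0.20 lower in KO, and matrix and recruited macrophage scores were 0.39 and 0.40 higher. A like rise of all other cells was argued against for endothelial cells, whose list fell with a median of -0.217. Kupffer scores were 0.16 lower too. The score of cholangiocytes minus that of endothelial cells rose by 1.35 (exact permutation p = 0.0286). That p adds nothing, since both scores already lay fully apart in opposite directions. A rise of that size on chow too was argued against by medians there of 0.23 with all libraries (camera adjusted p = 0.98), -0.37 without KO chow replicates 1 and 7 (camera adjusted p = 0.041) and -0.0954 without the 4 libraries rich in Dmbt1 (camera adjusted p = 0.45). More duct cells or duct-like hepatocytes remain as a hypothesis, and staining of ducts could test it.

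Divisions of the libraries set in advance gave these values for the other comparisons: on HFMCD 1 of 35, the real 1, reached 50 genes (highest other 1). For HFMCD against chow 1 of 100 in WT reached 9803 (highest other 4991), and 1 of 100 in KO reached 10920 (highest other 3535). For the difference of the KO effect 100 of 100 reached the real count of 0 (highest other 2), as any division must, so this decides nothing.

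Single libraries far from the rest of their group were sought in 240 groups of values; 13 were found, and chance would give about 1 in 20, or 12. List scores found were 5.07 for endothelial cells in KO HFMCD replicate 4, 6.24 for bile acid genes in KO HFMCD replicate 2 and 3.40 for the circadian clock in WT chow replicate 1. On chow, Hells stood at 7.23 CPM in KO replicate 6, Cyp2c70 at 549.9 CPM in KO replicate 2, Lrrc14b at 4.33 CPM in KO replicate 7 and Slc6a16 at 5.65 CPM in WT replicate 6 and 3.08 CPM in KO replicate 2. Ugdh stood at 238 CPM in WT chow replicate 3 and Elovl3 at 3.81 CPM in WT chow replicate 1. On HFMCD, Sftpd stood at 4.64 CPM and Angptl6 at 5.06 CPM in KO replicate 4, and Pkhd1 at 12.6 CPM in KO replicate 3.

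The KO effect of 7 lists differed between diets. Camera adjusted p-values were 1.42e-10 for cholangiocytes, 4.10e-06 for pericentral hepatocytes, 3.77e-05 for endothelial cells, 1.48e-04 for both interferon-stimulated and xenobiotic genes, 0.00641 for hepatocyte identity and 0.00852 for recruited macrophages. None kept its call with an estimated correlation, where the adjusted p ran from 0.0592 to 0.645.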

How the results depend on the processing

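No called named gene reversed its direction under DESeq2, RLE or upper-quartile scaling, the compared groups alone or libraries left out. These were the settings with values per gene. A change of sign was counted only where the gene was called in the main fit or in the alternative. Scaling by RLE or upper quartile moved the median log2 fold change of a comparison by at most 0.077. No paired analysis was possible because replicate numbers only follow the order of the labels and name no pairs.

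KO against WT on chow gave 340 genes. RLE scaling gave 330, upper quartile 302, no filter 299 and the stricter filter 347. DESeq2 gave 715, limma-voom with quality weights 113, the added fold threshold 44 by its construction and the 2 chow groups alone 2. Among alternatives chosen after seeing the data, 144 were called without KO chow replicates 1 and 7, 189 without the 4 libraries rich in Dmbt1 and 170 with a variance per group. Single libraries left out gave 49 to 611. For the tools the cause was not tested.

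KO against WT on HFMCD gave 50 genes. The stricter filter gave 56 and the added fold threshold 36. DESeq2 gave 185, limma-voom with quality weights 3.2e+02 (235 higher and 86 lower), RLE scaling 32, upper quartile 28, no filter 28 and the 2 HFMCD groups alone 296, and a variance per group, chosen after seeing the data, gave 257. Single libraries left out gave 1 to 16, with fewer samples in groups of 4. Otherwise the cause was not tested.

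HFMCD against chow gave 9803 genes in WT and 10920 in KO. Only the added fold threshold moved these by more than 1.5 times, to 4409 and 5180 by its construction; the other settings gave 8962 to 10820 in WT and 9837 to 12236 in KO. Single libraries left out gave 9246 to 9632 in WT and 10409 to 10916 in KO.

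The difference of the KO effect gave 0 genes with edgeR, with 1581 at an unadjusted p under 0.05. DESeq2 gave 100, limma-voom with quality weights 10 and no filter 5; of those chosen after seeing the data, 84 were called without KO chow replicates 1 and 7, 62 without the 4 libraries rich in Dmbt1 and 2 with a variance per group. Single libraries left out gave 0 to 8, and the cause was not tested. The overlap of lower genes in both diets was 2, with 11 by DESeq2, 1 with each diet fitted alone and 1 to 3 with single libraries left out, and the cause was not tested.

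Of 9 lists called on chow, camera with an estimated correlation called 0, fry 0, and the chow groups alone 2; single libraries left out gave 4 to 9. The fit without KO chow replicates 1 and 7, chosen after seeing the data, called 4, which were 3 of the 9 and the cholangiocyte list, lower with an adjusted p = 0.041. There the matrix list reversed, with an adjusted p = 0.355. Without the 4 libraries rich in Dmbt1, also chosen after seeing the data, 6 were called, 3 of them among the 9; the others were recruited macrophages (median -0.29, adjusted p = 0.037) and neutrophils (-0.77, adjusted p = 0.038), both lower, and xenobiotic metabolism (0.35, adjusted p = 0.010), higher. Of 16 on HFMCD an estimated correlation left 2 and fry 6, with 14 to 17 for single libraries left out. For diet, 15 in WT became 0 with an estimated correlation and 28 by fry, with 14 to 15 for single libraries left out, and 14 in KO became 0 and 27, with 13 to 14. For the difference of the KO effect, 7 became 0 with an estimated correlation and 2 by fry, with 7 to 10 for single libraries left out, and 11 without the 4 libraries rich in Dmbt1. An estimated correlation widens the error of a list where the estimate lies above the preset 0.01. The cause of these changes was not tested.

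Small changes were the least often recovered, and depth was not varied: of simulated changes of 0.5 on the log2 scale, 17.9% were recovered for KO against WT on HFMCD, 50.7% for KO against WT on chow and 13.4% for the difference of the KO effect.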

Other observations

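The list set as neighbours of Mboat7 on chromosome 7 also holds Lilrb4a, which lies elsewhere in the mouse. Of its 10 tested genes, 0 were called in KO on either diet over all genes. When adjusted over the list alone, 1 was higher on HFMCD, and the medians were 0.04 on chow and 0.01 on HFMCD. On HFMCD against chow 5 of the 10 genes fell and 1 rose in WT, among them Leng8 (-2.25) and Tmc4 (-2.31). Phospholipid remodelling genes were called higher in 9 and lower in 5 of 25 by diet in WT, with Lpcat2 at 2.42, Pla2g4a at 2.30 and Pnpla6 at -1.44, and higher in 14 and lower in 4 in KO. Genes of methionine and choline metabolism were higher in 5 and lower in 10 of 22 in WT, with Pcyt2 at -1.11 and Nnmt at -1.63. Clock genes were higher in 1 and lower in 7 of 16 in WT, with Per1 at -1.87. Xist, which is transcribed from the inactive X chromosome of female cells, stood at 119 to 1024 CPM in every library. The labels do not state the sex, but Xist at these levels goes with female mice throughout. Kupffer cell genes were higher in 11 and lower in 1 of 14 by diet in WT, lymphocyte genes higher in 16 of 20, interferon-stimulated genes higher in 16 and lower in 2 of 20, NRF2 targets higher in 11 and lower in 1 of 17 and endothelial genes higher in 10 of 16.

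Marker lists of tissues were summed in CPM. Gallbladder and gland mucosa (5 genes, 4 tested, 0 in the fixed lists) stood at 125 and 64.7 in KO chow replicates 1 and 7, 48.6 and 32.1 in WT chow replicates 3 and 5, 0 to 1.44 in the other chow livers, 0.041 to 0.242 in WT on HFMCD and 0.471 to 2.02 in KO on HFMCD. Skeletal muscle (12 genes, 5 tested, 0 in the fixed lists) stood at 2408 in KO chow replicate 7 and at most 6.19 elsewhere. Smooth muscle (8 genes, 8 tested, 2 in the fixed lists) stood at 221, 186 and 195 in KO chow replicates 1 and 7 and WT chow replicate 3, and at 70.8 to 141 in the other chow livers. Mesothelium (5 genes, 5 tested, 0 in the fixed lists) stood at 5.64 and 5.84 in KO chow replicates 1 and 7, 0.566 to 3.24 in the other chow livers and 2.51 to 9.19 on HFMCD. Fasting-induced genes (16 genes, 16 tested, 15 in the fixed lists) stood at 26072 to 49384 in WT on chow, 20194 to 28771 in KO on chow and 6420 to 14787 on HFMCD. Nuclear long RNAs (4 genes, 4 tested, 1 in the fixed lists) stood at 2344 to 3489 on chow and 605 to 1042 on HFMCD.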
